A study of Homo sapiens with 14 samples.

How the data were processed

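HTR8/SVneo cells with METTL3 knockdown and control cells, all kept in 30 mM glucose for 24 h, were profiled by METTL3, ARID1A and H3K27ac ChIP-seq, each with input DNA, and by ATAC-seq. Groups were taken from the sample titles: each assay and condition is a group of 1 library, which gives 14 groups. Peak lists of 8 libraries were used, and the 6 input libraries were not analysed here. Peaks were called per library.

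The METTL3 lists were made with HOMER findPeaks in its factor mode, at a false discovery rate of 0.05 and with local filters of 4-fold and a Poisson p of 0.0001 over 10000 bp, per the file headers. The recorded command names no input library. The headers give 15029608 tags for the control and 13517422 for the knockdown, peak sizes of 206 and 255 bp, and thresholds of 9 and 10 tags. The deposited METTL3 lists hold positions and a score column that is constant, so row order was used as rank, on the assumption that HOMER's usual order from strong to weak was kept.

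The ARID1A, H3K27ac and ATAC lists are in the narrowPeak format of MACS2, which the submitters' processing notes name. For each peak the authors deposited the fold enrichment over local background, a ratio, together with the -log10 p and -log10 q at the summit. The smallest -log10 q in each list was just above 2. MACS2 settings, the use of the input libraries, duplicate handling and any shift of ATAC reads are not given in the sources used here. The submitters' processing notes also name Subread 2.0.0, cutadapt, Trim Galore and FastQC, without their roles, and the genome build hg19. Fold enrichments, -log10 p values and ranks were used within a list to describe, rank, filter and match peaks. Fold and -log10 p also gave the recovered reads and backgrounds, described below, which were compared between libraries.

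Peaks of a list that overlapped would have been merged, and none did. A control peak was called retained when at least 1 bp overlapped a knockdown peak of the same assay, and otherwise lost. A knockdown peak without such an overlap was called knockdown-only. A lost peak is a peak that was not called, which depends on depth and threshold and does not show an absent signal. Shares carry Wilson 95% intervals over peaks. Neighbouring peaks and reads are not independent molecules, so these intervals cover counting error only. Chance overlap was taken from 1000 circular shifts along each chromosome, of the knockdown list for retention and of the METTL3 list for overlap between assays.

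Retention at one class of sites was compared with other sites in the same 1 of 10 ranges of fold and of 10 ranges of width. Intervals of these differences are the central 95% of 1000 draws that resampled both sides. For lost against retained peaks, 7 ARID1A sites had no matched site in the comparison of H3K27ac and were left out. On simulated lists of 26155 peaks with a true difference of 20 points, the matched estimate was 19.4 points and the unmatched one 29.3. With a true difference of 0 points they were -0.832 and 9.18. In these simulated lists the site class and the background retention depended only on the fold range that was matched. They therefore cannot show how matching does where another property matters.

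Read totals of the MACS2 libraries are not given, so depth was inferred from a background recovered from the lists. Such a background also depends on fragment length and on any scaling to an input library, both unknown here. The deposited fold and -log10 p of a peak fix a whole number of summit reads and a local background, given a pseudocount of 1 read. Both were found within a tolerance of 0.001 for 99.988 to 100% of the peaks of each list. The smallest local background was taken as the genome background: 1.58 and 1.20 reads in the ARID1A control and knockdown, 2.94 and 2.74 in H3K27ac, and 1.03 and 2.36 in ATAC. The summit reads of the library with the higher background were thinned 20 times to the background of the other and peaks were counted again. On simulated libraries of 60000 sites, the deep over shallow ratio of peaks with a -log10 p of at least 10 went from 1.56 to 1.00, and at a -log10 p of at least 4 from 1.17 to 0.996. The simulation holds no rule on peak width. Thinning acts on called summits and does not repeat the caller's rule on peak width.

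Before the data were examined, the results, their tests and alternatives were fixed: the upper 50% of each list, lists of equal length, an overlap of 50% of the shorter peak, peaks within 500 bp, no matching, -log10 q of at least 10, entries as deposited and base pairs covered. Thinning, matching on -log10 p, accessible peaks alone and the removal of the short arm of chromosome 5 were added after the data were seen. Named regions follow a rule fixed beforehand: the 10 control-only and 10 knockdown-only peaks of highest rank per assay, at least 150 bp wide, on chromosomes 1 to 22 and X, of which the text gives the strongest. A further part of the rule, 20 sites where METTL3 and ARID1A were lost together, was written for promoters and was applied to all sites. Windows, chromosome 5, the longest stretches without peaks and the widest H3K27ac peaks were chosen after their values were seen.

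The gene table at hand is of GRCh38, a different build, so no position was assigned to a gene. The 5 planned results on promoters and gene lists were therefore not run, and the METTL3 and ARID1A genes were not located. Expression was not measured here, so the METTL3 peak lists are the only view of the knockdown itself. Arms of chromosome 5 were split at its longest stretch without a peak in any list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.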

Results

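HTR8/SVneo cells, an immortalized trophoblast line from first-trimester placenta, were profiled after 24 h in 30 mM glucose, with METTL3 knocked down or in control cells. METTL3 is the catalytic subunit of the RNA m6A methyltransferase. Its position on chromatin was mapped by ChIP-seq. ChIP-seq also mapped ARID1A, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, and H3K27ac, a histone mark of active promoters and enhancers. ATAC-seq mapped accessible DNA. The 14 libraries comprised 14 groups of 1 library each, and 8 of them had a peak list, a control and a knockdown list for each of the 4 assays; the 6 input libraries were not analysed here. No group had a replicate, so no difference between conditions could be set against a spread between replicates and no p-value is given. Intervals are 95% Wilson intervals over peaks, which cover counting error only, and every statement describes these libraries. Positions are hg19 coordinates.

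The knockdown list of METTL3 peaks was short, and apart from its first rows few of its peaks had a counterpart in the control list. The control library gave 8628 METTL3 peaks and the knockdown library 1818, a ratio of 0.211, from 15029608 and 13517422 tags. Of the control peaks, 270 overlapped a knockdown peak, or 3.13% (2.78 to 3.52%), against a median of 0.0348% when the knockdown peaks were shifted along the chromosomes. Of the knockdown peaks, 1548, or 85.1% (83.4 to 86.7%), had no counterpart in the control. Tags inside peaks made up 0.885% of all tags in the control and 0.310% in the knockdown. Before these lists were final, HOMER's local filter had removed 10528 of 19156 putative control peaks and 5459 of 7277 putative knockdown peaks. Retention was highest among the strongest 10% of the control list, at 21.6% (18.96 to 24.4%), and lay between 0.463% and 2.09% in the 9 groups of lower rank. Of the first 10% of the knockdown list, 92.3% (87.4 to 95.3%) had a control counterpart. Retention of control peaks rose to 5.01% when only the upper 50% of each list was used and to 11.2% with both lists at 1818 peaks. In the latter case 88.8% of the knockdown peaks had no counterpart. That share could not fall, because only the control list was cut.

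**Figure D1:**
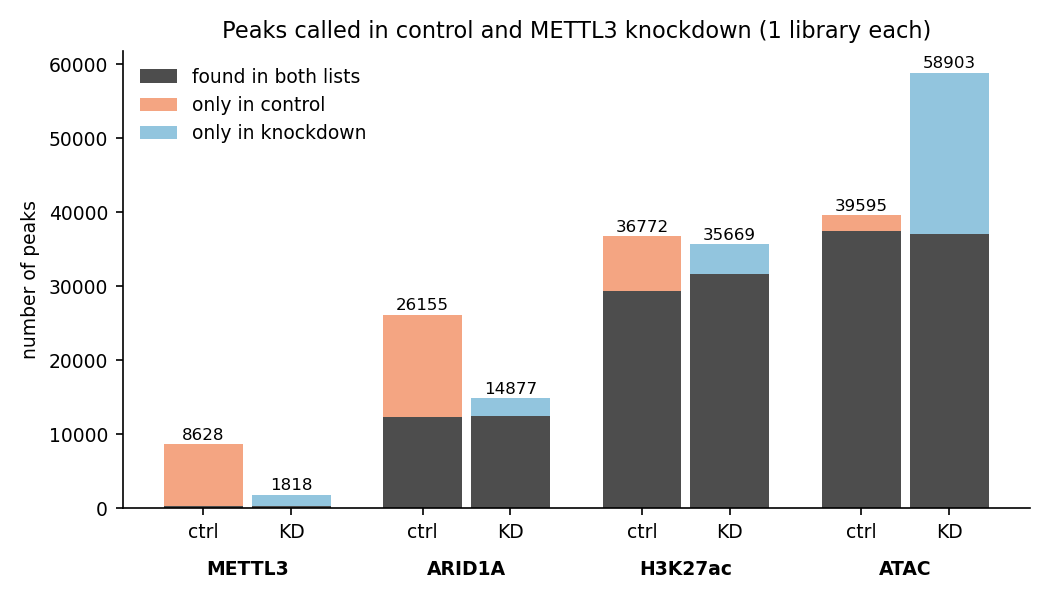
Number of peaks (vertical axis) called in the control (ctrl) and METTL3 knockdown (KD) library of each assay, 1 library per bar. Dark grey marks peaks that overlap a peak of the other list by at least 1 bp, and colour marks peaks found in 1 list: 8358 of the 8628 control METTL3 peaks and 21842 of the 58903 knockdown ATAC peaks.

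In control cells, most METTL3 peaks overlapped ATAC and H3K27ac peaks. ATAC peaks covered 83.1% (82.3 to 83.9%) of the 8628 METTL3 peaks, H3K27ac peaks 69.8% (68.8 to 70.8%) and ARID1A peaks 34.3% (33.3 to 35.3%). METTL3 peaks shifted along their chromosomes reached medians of 1.32%, 2.42% and 0.684%, and in none of 1000 shifts was the overlap as high. The most frequent combination was ATAC with H3K27ac and without ARID1A, at 3566 METTL3 peaks, followed by all 3 features together, at 2068. The overlap with ARID1A was 22.2% in the upper 50% of each list. The recorded HOMER command names no input library, so these overlaps do not separate METTL3 binding from uneven recovery of DNA at open sites.

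The METTL3 peaks of the knockdown overlapped these features less often, though more often than shifted peaks. Of the 1818, 23.9% (22.02 to 25.9%) overlapped an ATAC peak of the knockdown cells, 11.3% (9.90 to 12.8%) an H3K27ac peak and 1.16% (0.757 to 1.76%) an ARID1A peak. Medians of shifted peaks were 2.09%, 2.04% and 0.385%, and in none of 1000 shifts was the overlap as high. Among control METTL3 sites that carried ATAC, H3K27ac and ARID1A, 3 of 2068 were retained, or 0.145% (0.0493 to 0.426%). Among the 915 sites with none of these features, 130 were retained, or 14.2% (12.1 to 16.6%). These classes were not matched on rank. Of all 270 retained METTL3 peaks, 124 lay within 2 Mb of the longest stretch of their chromosome without a peak in any list. The 1-Mb window with the most control-only METTL3 peaks was chromosome 6, 26000001 to 27000000, where all 28 were without a counterpart.

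**Figure D2:**
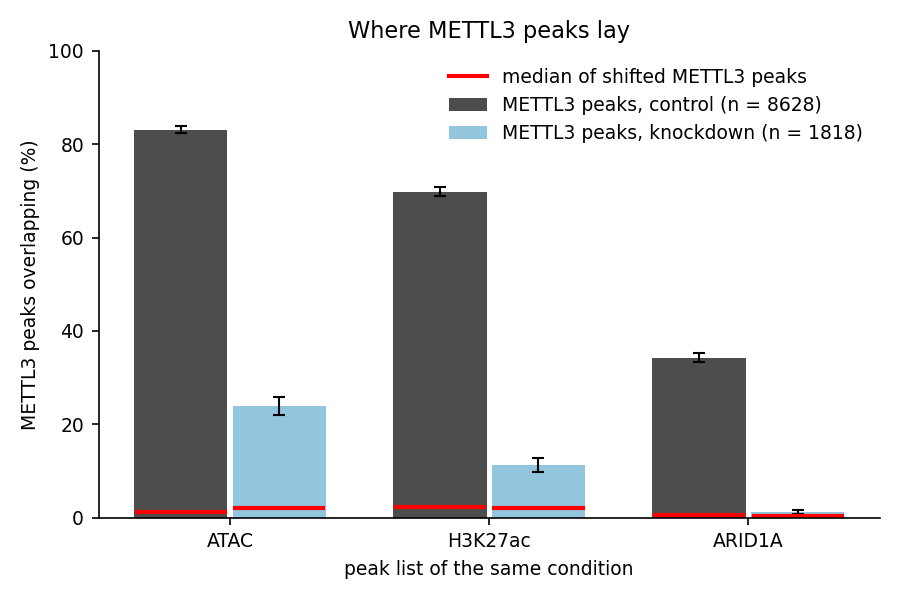
Percent of METTL3 peaks (vertical axis) that overlap a peak of each other assay in the same condition, for the control (grey) and knockdown (blue) list. Error bars are 95% Wilson intervals over peaks and red lines the median of 1000 shifts; for ATAC, the overlap is 83.1% in the control and 23.9% in the knockdown.

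Few of the strongest METTL3 peaks found in 1 condition overlapped H3K27ac. The first control-only peak was at chromosome 6, 58778558 to 58778764, and the second at chromosome 1, 121483982 to 121484188. Both overlapped ATAC peaks of both conditions. All 10 strongest control-only peaks lay at most 41.3 kb from the longest peak-free stretch of their chromosome, and 3 of the 10 strongest knockdown-only peaks lay within 2 Mb of it. Chromosome 16 held 4 of the 10 strongest control-only peaks, between 46395209 and 46427467, and 1 of the 10 overlapped an H3K27ac peak, in the knockdown. Of the 10 strongest knockdown-only peaks, the first lay at chromosome 2, 133029544 to 133029798, and none overlapped an H3K27ac or ARID1A peak. The deposited METTL3 lists carry no strength per peak, and this ranking follows the row order of the lists. Whether the peaks next to the peak-free stretches mark METTL3 binding was not tested, and the recorded HOMER command names no input library.

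ARID1A had fewer peaks after METTL3 knockdown, and sites with neither an ATAC nor an H3K27ac peak were retained least often. The lists held 26155 peaks in the control and 14877 in the knockdown, a ratio of 0.569, and covered 14.3 and 7.10 Mb. Of the control peaks, 47.2% (46.6 to 47.8%) were retained, against a median of 0.524% for shifted peaks. Retention was 71.5% (70.6 to 72.4%) at the 10058 sites with ATAC and H3K27ac, 49.2% (47.2 to 51.2%) at sites with ATAC alone and 40.8% (39.6 to 42.0%) with H3K27ac alone. At the 7469 sites with neither it was 19.1% (18.2 to 20.0%). These classes were not matched on fold or width. The genome background recovered from the knockdown ARID1A list was 0.763 times that of the control, and read totals of these libraries are not given. After the recovered control reads were thinned to that background, the ratio of peak numbers was 0.611.

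**Figure D3:**
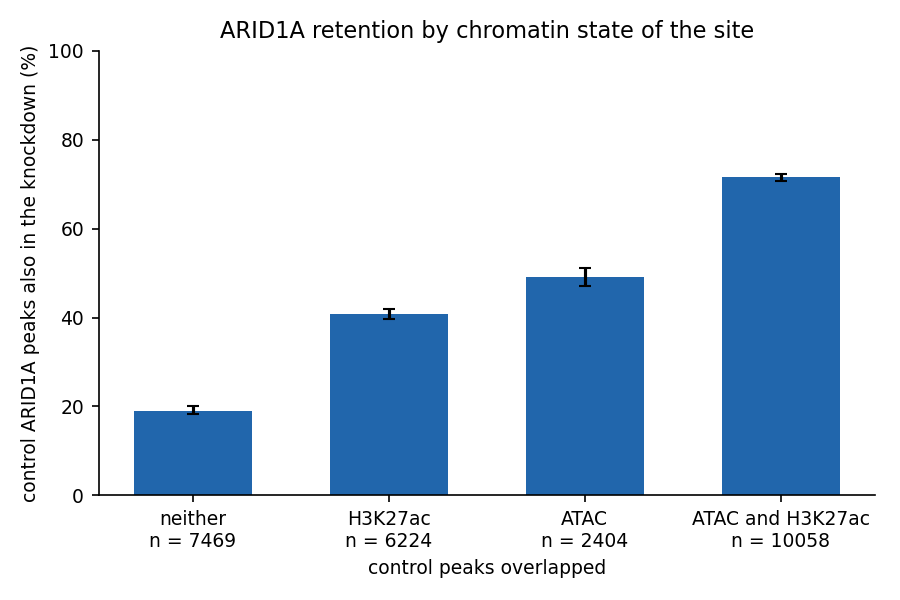
Percent of control ARID1A peaks also called in the knockdown (vertical axis), by which control ATAC and H3K27ac peaks the site overlapped. Bars are 1 pair of libraries with 95% Wilson intervals over peaks, and retention runs from 19.1% with neither to 71.5% with both. The classes were not matched on fold or width.

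The 2392 ARID1A peaks found only in the knockdown were 16.1% (15.5 to 16.7%) of its list, and 70.2% (68.3 to 72.0%) of them overlapped a knockdown ATAC peak. With both lists at 14877 peaks, 42.4% of the knockdown peaks had no counterpart. This share could not fall, because only the control list was cut. In the upper 50% of each list, where both were cut, it was 28.0%. The strongest control-only peak lay at chromosome 3, 105689134 to 105689783, with a fold of 21.3 over background. The strongest knockdown-only peaks, tied at a fold of 13.6, lay at chromosome 13, 109909230 to 109909906, and at chromosome 2, 112165273 to 112165652. The latter overlapped a control METTL3 peak. Fold enrichments are the authors' own, and folds of different lists were not compared. The 1-Mb window with the most control-only ARID1A peaks was chromosome 12, 20000001 to 21000000, where 59 of 82 peaks were without a counterpart. The next were chromosome 3 between 1000001 and 2000000, with 48 of 65, and chromosome 5 between 21000001 and 22000000, with 42 of 57. The chromosome 5 window lies on the short arm. There the recovered ARID1A background was 1.17 times that of the other arms pooled in the control and 2.17 times in the knockdown. The same window held the most knockdown-only ATAC peaks, 37 of 63.

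Most control ARID1A peaks that lay at METTL3 sites were called again in the knockdown. Of the 2932 control ARID1A peaks that overlapped a METTL3 peak, 84.5% were retained, against 57.2% of other ARID1A peaks of equal score and width, a difference of 27.3 percentage points (25.2 to 29.5). The difference was 42.1 points without matching, 15.8 points when peaks were matched on -log10 p in place of fold, and 17.1 points among accessible peaks alone. At 447 of the 2932 sites, both ARID1A and METTL3 were without a peak in the knockdown. Of the 20 such sites with the strongest ARID1A peak, 13 had an H3K27ac peak and 13 an ATAC peak in the knockdown. The first was at chromosome 9, 29556194 to 29556776, with none of the other features, and the second at chromosome 5, 52658388 to 52658970, with ATAC and H3K27ac in both conditions.

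H3K27ac differed least in number of peaks when whole lists were counted, and its strong peaks were nearly all found in both conditions. The control list held 36772 peaks and the knockdown list 35669, a ratio of 0.970, covering 58.1 and 49.8 Mb. The ratio was 0.917 among peaks with a -log10 p of at least 10. At a -log10 p of at least 30 it was 0.860, and 0.887 after the control reads were thinned. Of the control peaks, 79.8% (79.4 to 80.2%) were retained, and 11.3% (11.002 to 11.7%) of the knockdown peaks had no counterpart. Retention was nearly complete in the strongest 10%, at 99.97%, and 41.4% (39.9 to 43.0%) in the weakest. H3K27ac peaks with an ATAC and an ARID1A peak were retained at 92.1% (91.6 to 92.7%) and those with neither at 48.5% (47.4 to 49.6%). These classes were not matched on fold or width. Overlap with a control ATAC peak itself fell from 96.4% in the strongest 10% to 35.7% in the weakest. The strongest control-only peak lay at chromosome 16, 58861759 to 58864372, with a fold of 21.2, where an ARID1A peak was also called in the control only and an ATAC peak in the knockdown only. The strongest knockdown-only peak lay at chromosome 2, 50783501 to 50785320, with a fold of 11.2, where ARID1A and ATAC peaks were likewise called only in the knockdown.

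At METTL3 sites, 97.2% of the 5856 H3K27ac peaks were retained, against 93.5% of other H3K27ac peaks of equal score and width, a difference of 3.66 points (3.06 to 4.30). Without matching the difference was 20.7 points, and matched on -log10 p it was 1.33 points. Among accessible peaks alone it was 2.07 points.

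**Figure D4:**
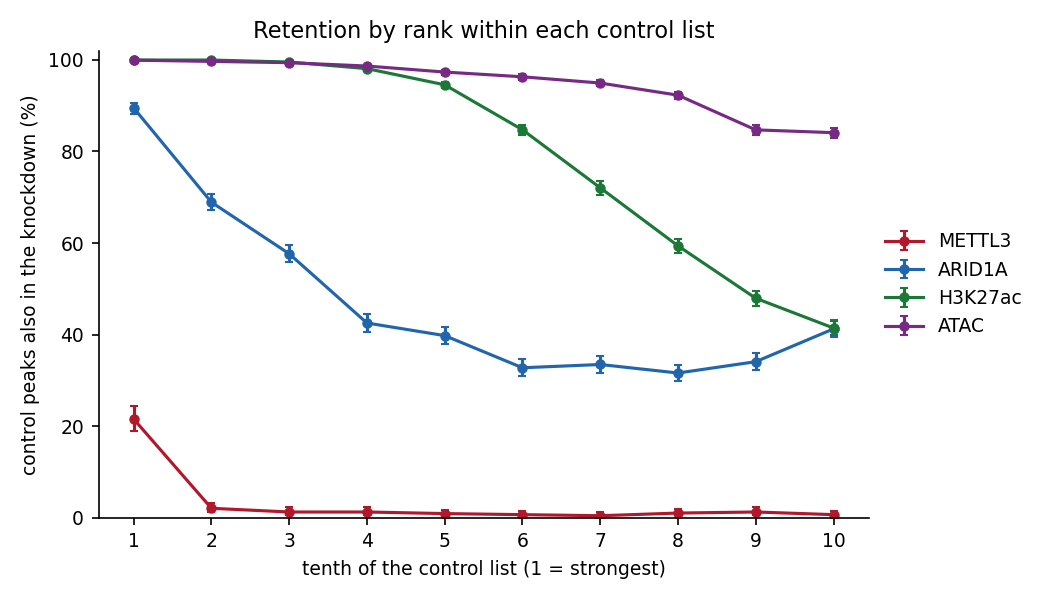
Percent of control peaks also called in the knockdown (vertical axis) for each 10% of the control list, from the strongest (1) to the weakest (10), with 95% Wilson intervals over peaks. Peaks are ranked by the authors' fold or, for METTL3, by row order; H3K27ac runs from 99.97% to 41.4% and METTL3 from 21.6% to 0.696%.

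Most control ATAC peaks were called again in the knockdown, whose list was longer. The ATAC lists held 39595 control and 58903 knockdown peaks, a ratio of 1.49, covering 26.6 and 41.7 Mb. Of the control peaks, 94.7% (94.5 to 94.96%) were retained, and 37.1% (36.7 to 37.5%) of the knockdown peaks had no counterpart. These 21842 knockdown-only peaks overlapped a knockdown H3K27ac peak in 19.8% (19.3 to 20.4%) of cases, against 62.4% (61.9 to 62.9%) of the shared peaks. They overlapped a knockdown ARID1A peak in 10.1% (9.74 to 10.5%), against 25.3% (24.8 to 25.7%).

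The strongest knockdown-only ATAC peak lay at chromosome 16, 2610694 to 2611143, with a fold of 17.9, and the strongest control-only peak at chromosome 3, 141179044 to 141179373, with a fold of 12.4. Neither overlapped a peak of another assay. The genome background recovered from the knockdown ATAC list was 2.29 times that of the control. After the recovered knockdown reads were thinned to the control background, the ratio of peak numbers was 1.26 at the lowest -log10 p of the control list and 0.958 among peaks with a -log10 p of at least 10. Of the thinned knockdown peaks in that stronger set, 10.3% had no counterpart in the control list, which was not cut for this share. The share was taken from the first thinning draw. With both lists at 39595 peaks, 77.6% (77.2 to 78.0%) of the control peaks were retained and 23.2% of the knockdown peaks had no counterpart. Only the knockdown list was cut, so this retention could not rise.

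Nearly all control ATAC peaks that lay at METTL3 sites were called again in the knockdown. Of the 7039 control ATAC peaks at METTL3 sites, 99.7% were retained, against 98.3% of other ATAC peaks of equal score and width, a difference of 1.35 points (1.02 to 1.66). The difference was 5.98 points without matching, 0.844 points when matched on -log10 p and -0.772 points (-2.09 to 0.571) with lists of equal length. At the 8358 METTL3 sites without a knockdown peak, the ATAC peak was retained at 99.7% (99.5 to 99.8%) of those that had one, the H3K27ac peak at 97.3% (96.8 to 97.7%) and the ARID1A peak at 84.7% (83.4 to 86.0%). At the 2332 control ATAC peaks that carried METTL3, ARID1A and H3K27ac, METTL3 was kept at 5 sites, ARID1A at 2039, H3K27ac at 2233 and ATAC at 2326.

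Sites that lost an ARID1A peak kept their other features slightly less often. Where the ARID1A peak was lost, the overlapping H3K27ac peak was retained at 82.8%, against 89.9% at matched sites that kept ARID1A, a difference of -7.12 points (-8.33 to -5.96). The overlapping ATAC peak was retained at 93.3%, against 97.3%, a difference of -3.98 points (-4.97 to -2.98). Without matching the H3K27ac difference was -10.96 points, and with lists of equal length the ATAC difference was -6.91 points. Where an H3K27ac peak was lost, the ATAC peak was retained at 94.8%, against 97.8%, a difference of -2.96 points (-4.02 to -1.88). In the upper 50% of each list this difference was 0.303 points (-1.24 to 1.86).

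The short arm of chromosome 5 stood apart in the METTL3 knockdown list. The arm, taken up to position 46379816 where the longest stretch without a peak began, held 362 of the 1818 knockdown METTL3 peaks, or 19.9% (18.1 to 21.8%). In the control it held 213 of 8628, or 2.47% (2.16 to 2.82%). On the long arm the shares were 2.86% (2.19 to 3.73%) and 4.10% (3.70 to 4.54%). The 362 peaks overlapped a knockdown ATAC peak in 9.67% (7.03 to 13.1%) and an H3K27ac peak in 1.93% (0.940 to 3.94%). For the 1456 knockdown METTL3 peaks elsewhere the shares were 27.5% and 13.6%. The median recovered H3K27ac background at peaks of this arm was 2.06 times that of all other arms pooled in the control and 1.56 times in the knockdown. For ATAC it was 1.05 and 0.905 times. Without the arm, the ratio of METTL3 peak numbers was 0.173.

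**Figure D5:**
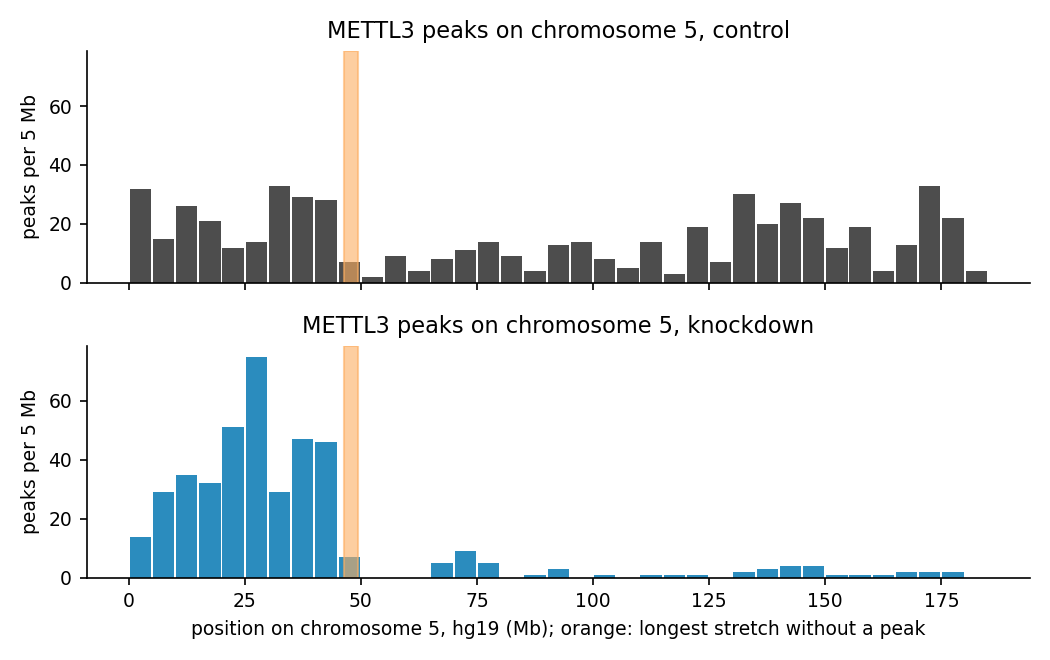
Number of METTL3 peaks in each 5-Mb bin (vertical axis) along chromosome 5 in hg19 (horizontal axis, Mb), for the control and the knockdown library. The orange band is the longest stretch without a peak in any list, from 46379817 to 49405705; 362 knockdown peaks lie to its left and 52 to its right.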

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

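The results on thinned reads, on matching by -log10 p, on accessible peaks alone and without the short arm of chromosome 5 were chosen after the data were seen, and the other alternatives in this part were fixed before the data were examined. No paired analysis was possible because each group held 1 library. Of 108 alternative values of 21 results, 37 stayed within the counting interval of the reported value or within 1.5 times a ratio of peak numbers, 68 moved beyond it and 3 changed sign (the counting intervals are narrow). Except where stated, the cause was not tested. The alternatives on promoters were not run for want of a gene annotation of the build, and a score cut of the METTL3 lists was not run because their score is constant. Depth limits every lost or gained peak: a peak near the threshold of the shallower library cannot be called absent. For ARID1A, H3K27ac and ATAC, depth was inferred from the recovered background, and read totals are not given.

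In the upper 50% of each list, retention was 5.01, 40.6, 81.4 and 93.6% for METTL3, ARID1A, H3K27ac and ATAC, and knockdown-only shares were 76.2, 28.0 and 13.2% for the first 3. METTL3 overlap was 22.2, 65.9 and 62.7% for ARID1A, H3K27ac and ATAC, and the differences at METTL3 sites were 24.0 points for ARID1A and 4.56 for H3K27ac. Differences at lost ARID1A peaks were -8.67 points for H3K27ac and -5.16 for ATAC. At lost H3K27ac peaks the ATAC difference was 0.303 points (-1.24 to 1.86), a change of sign whose cause was not tested.

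With lists of equal length, retention was 11.2, 56.5, 81.0 and 77.6% for METTL3, ARID1A, H3K27ac and ATAC, and knockdown-only shares were 88.8, 42.4, 12.4 and 23.2%. Only the longer list was cut: the control list for METTL3, ARID1A and H3K27ac, and the knockdown list for ATAC. The knockdown-only shares of METTL3, ARID1A and H3K27ac therefore could not fall, and ATAC retention could not rise. METTL3 overlap was 25.4, 74.7 and 88.4% for ARID1A, H3K27ac and ATAC. The differences at METTL3 sites were 23.2, 2.85 and -0.772 points. The last, with an interval of -2.09 to 0.571, was a change of sign whose cause was not tested. At lost ARID1A peaks they were -9.11 points for H3K27ac and -6.91 for ATAC.

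With an overlap of 50% of the shorter peak, retention was 78.9 and 93.8% for H3K27ac and ATAC. Knockdown-only shares were 86.7, 16.97, 12.5 and 37.7% for METTL3, ARID1A, H3K27ac and ATAC, METTL3 overlap was 33.2, 64.8 and 80.3% for ARID1A, H3K27ac and ATAC, and the H3K27ac difference at METTL3 sites was 3.03 points. For peaks within 500 bp, the values in the same order were 3.81, 48.3, 82.1 and 95.01% for retention, 82.5, 15.3, 9.20 and 36.6% for knockdown-only shares, 35.5, 75.6 and 84.7% for METTL3 overlap, and 5.28 points.

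Without matching, the differences at METTL3 sites were 42.1, 20.7 and 5.98 points for ARID1A, H3K27ac and ATAC. At lost ARID1A peaks they were -10.96 points for H3K27ac and -5.04 for ATAC, and at lost H3K27ac peaks -4.13 points. Matched on -log10 p, the differences at METTL3 sites were 15.8, 1.33 and 0.844 points, and among accessible peaks alone 17.1 points for ARID1A and 2.07 for H3K27ac.

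Without the short arm of chromosome 5, the METTL3 knockdown-only share was 82.2%. After thinning to equal background, ARID1A retention was 49.6% and the ATAC knockdown-only share 29.3%. With a -log10 p of at least 10 as well, ARID1A and H3K27ac retention were 67.0 and 90.9% and the ATAC knockdown-only share was 10.3%. For these shares only the thinned list was cut at 10, and the other list was used whole. Shares after thinning were taken from the first thinning draw, and ratios from the mean of all draws. With each list cut at 10 after thinning, the ATAC ratio of peak numbers was 0.958, a change of sign on the log scale against 1.49. Thinning alone gave an ATAC ratio of 1.26 and the cut of 10 alone 1.52, so the change of sign came only with both.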

Other observations

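The test of ATAC peaks with a -log10 p of at least 10 was chosen after the result was seen, as were the other thresholds of the thinned counts and the test of an ARID1A loss confined to METTL3 sites, which replaced one whose outcome the list lengths limited, and the other tests of explanations were fixed before their results were seen; the widest H3K27ac peaks, the windows, the stretches without peaks and chromosome 5 were chosen as topics after their values were seen. The widest H3K27ac peaks held a METTL3 peak more often than the others, but fewer METTL3 peaks per megabase. The 1839 widest control peaks, 5% of the list and at least 4241 bp wide, were retained at 99.5%, which an overlap of 1 bp makes easy for wide peaks, and 73.1% overlapped an ARID1A peak. The median width of the widest 5% was 5406 bp in the control and 4843 bp in the knockdown. A METTL3 peak lay in 30.3% of the widest control peaks, against 15.2% of the other H3K27ac peaks, but per megabase they held 48.7 METTL3 peaks against 118. The groups were chosen by width and the density is divided by width, so the lower density does not show a depletion. The widest control peak spanned 30.6 kb at chromosome 5, 147558903 to 147589513, and was called in both conditions. The 1-Mb window with the most control-only H3K27ac peaks was on the X chromosome, 91000001 to 92000000, where 31 of 33 had no counterpart. The next were on chromosome 4 between 134000001 and 135000000, with 28 of 32.

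Many of the METTL3 peaks found in both conditions lay near the longest stretches without peaks. Within 2 Mb of such a stretch lay 124 of the 270 shared peaks, or 45.9% (40.1 to 51.9%), against 4.28% (3.87 to 4.72%) of all control peaks and 11.1% (9.75 to 12.6%) of all knockdown peaks. Of the first 100 peaks in row order, 66 in the control and 64 in the knockdown lay there. Of the first 10% of the knockdown list, 92.3% had a control counterpart, and of the last 10%, 3.87%.

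The knockdown ATAC library gave 1.49 times as many peaks as the control, with a recovered background 2.29 times that of the control. A deeper library as the whole cause, with depth inferred from that background, was given a bound beforehand: at least 25% more peaks than the control after thinning, at the lowest -log10 p of the control list, would count against it. The ratio was 1.26, past that bound. The bound was judged wrong after the value was seen, because between the lowest -log10 p and 5 the thinned list held 4159 summits against 375 in the control list, although simulated libraries without a rule on peak width gave 0.996 at a -log10 p of 4; depth and knockdown cannot be told apart for weak peaks. At a -log10 p of 6, 8, 10, 20 and 30 the thinned ratios were 1.09, 1.00, 0.958, 0.873 and 0.822, so for peaks of at least 10 depth may account for the excess, and an effect of the knockdown on accessibility stays open.

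The knockdown ARID1A library gave 0.569 times the control number of peaks. A shallower library is argued against as the whole cause, as far as the recovered background measures depth: after thinning, the control still gave 1.43 times as many peaks at the most favourable of 6 thresholds and 1.64 times at the lowest, beyond an excess of 25%, the bound set beforehand. Between the lowest -log10 p and 5 the thinned control list held 440 summits against 99 in the knockdown list. The value at the lowest threshold thus has the limit named for ATAC, and the 1.43, at a -log10 p of at least 10, lies above that range. A loss confined to METTL3 sites is also argued against, since at equal score and width ARID1A peaks at METTL3 sites were retained more often than others, by 27.3 points (25.2 to 29.5). Matched on -log10 p in place of fold, the difference was 15.8 points (14.1 to 17.8). A candidate explanation that remains is that many control ARID1A peaks lay outside accessible chromatin: at equal score and width, 43.2% of lost and 75.4% of retained peaks overlapped a knockdown ATAC peak, a difference of -32.2 points (-33.8 to -30.6). The score here was fold, and this difference was not computed with matching on -log10 p. Overlap of control ARID1A peaks with control ATAC peaks did not fall steadily with fold. It was 67.2% in the strongest 10%, 33.8% in the group of rank 6 of 10 and 68.4% in the weakest 10%. The knockdown ATAC list cannot tell a state of the control cells from an effect of the knockdown. With the control ATAC list and no matching, 29.6% of lost and 67.9% of retained peaks overlapped an ATAC peak. Whether the lost peaks outside accessible chromatin were weak true sites, background of 1 immunoprecipitation or an effect of the knockdown was not tested, with 1 library per condition.

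The short arm of chromosome 5 held 19.9% of the knockdown METTL3 peaks and 2.47% of the control ones. METTL3 binding at active sites of the arm is argued against for most of the 362 peaks, since 9.67% of them overlapped a knockdown ATAC peak. Among the 1456 knockdown METTL3 peaks outside the arm, 27.5% (25.2 to 29.8%) did. The overlap was thus low across this list and lower still on the arm. More DNA copies of the arm in these cells may contribute, because HOMER was run without input and the median recovered H3K27ac background on the arm was at least 1.56 times that of all other arms pooled in both libraries, though 2 other arms went different ways in the knockdown: the long arm of chromosome 20, at 1.66 times, held 2.48% of the knockdown METTL3 peaks against 2.93% of the control ones, and the short arm of chromosome 21, at 1.83 times over 9 H3K27ac peaks, held 0.990% against 0.185%. The ARID1A background was 1.17 and 2.17 times that of the pooled other arms in control and knockdown, and the ATAC background 1.05 and 0.905 times, so the lists do not all point one way. The arm held 1.90% of control and 2.35% of knockdown ATAC peaks, 2.77% and 2.08% of ARID1A peaks, and 1.08% and 1.17% of H3K27ac peaks. The control METTL3 share was thus above the control H3K27ac and ATAC shares and below the ARID1A share. The control cells would share an arm gain of the line. A copy gain alone therefore leaves open why the METTL3 excess was so much larger in the knockdown. A change in the knockdown cells was not tested.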
